A study of Homo sapiens with 11 samples.

How the data were processed

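RNA of IMR32 cells, a human neuroblastoma cell line with amplification of MYCN, was measured on 11 one-colour Affymetrix expression arrays. Per the labels, cells were transduced with lentivirus carrying either a control short hairpin RNA or a hairpin directed at MYCN and were collected 24, 48 or 72 hours later, and cells without virus were collected at 0 hours. The labels gave 2 arrays without virus, 1 control virus array at each of the 3 times, and 2 arrays labelled shMYCN (A and B) at each of the 3 times. The labels do not state in full that the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be partly technical.

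The authors deposited a linear signal intensity for each of 54675 probe sets on each array. The submitters' processing notes name MAS5 and GCOS, with no version given in the sources used here. From the values, the deposited intensity was scaled so that the mean of the middle 96 percent of probe sets was 100 on every array, so a change in the total RNA of a cell cannot be seen. Background correction and detection calls were not given in the sources used here. The genome build of the array was not given either, and no coordinates are printed. The number of arrays limits the precision of every value.

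Probe sets were named from the platform annotation. Of 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were unnamed here. Symbols of 41043 probe sets were updated through their Entrez gene number with the RefSeq table of assembly GRCh38.p14, used for names and neighbouring genes alone. The 62 control probe sets of the manufacturer were left out of all tests. A gene was represented by its probe set with the highest mean log2 signal over the 11 arrays, and the dimmest 40 percent of the 19775 genes were left out (mean signal under about 14.8), which left 11865 genes.

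Signals were analysed as log2(signal + 16), so folds of dim genes are understated. A mean for each of 7 groups was fitted over all 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend), with 4 residual and 7.35 prior degrees of freedom. The spread came from the 4 groups with 2 arrays, and the single control virus arrays were assumed to vary like them. In this fit each control virus array was a group of its own with independent error. Only the alternative with the culture series as a random block treated the 3 control virus arrays as 1 series, which the labels do not state. Apart from a one-sided, unadjusted Fisher exact test, all tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Errors beside log2 fold changes are standard errors of that fit. MYCN probe sets were tested in a fit of every probe set with 1 symbol, with no filter on dim ones, and adjusted over all of them.

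The 8 comparisons, the 25 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule took MYCN, the 12 largest rises and the 12 largest falls of the mean over 3 times among genes past the threshold whose 6 arrays labelled shMYCN lay on one side of the control array of their hour. It took the 5 largest in each direction in every other comparison, up to 4 members of each list by smallest p, and every measured member of the MYC network. Lists with at least 5 tested genes (23 of 25) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 769 distinct list genes, 601 were tested. Lists share some genes, so their results are not independent.

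The procedure was tested on simulated data with 200 changed genes. For the mean over 3 times, 49 of 50 genes changed 1.5-fold were recovered (98 percent). At each of 2-fold, 3-fold and 4-fold, 50 of 50 were recovered (100 percent). Beside these stood 16 false calls among the unchanged genes of the 11865 tested. At 24 hours, 54 percent of 1.5-fold and 92 percent of 2-fold changes were recovered, with 10 false calls. The simulated noise was independent and of equal size on every array, single controls included, so that assumption was not tested. Far fewer genes were changed in it than the 4500 called in the data.

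Alternatives were an offset of 1 or 64, quantile normalization, median scaling, no filter or a filter of 60 percent, the mean of all probe sets or each on its own, a variance model without trend, the letter A or B as a block, an additive model of virus and hour with and without the culture series as a random block, stricter thresholds, and leaving out arrays. One alternative for the MYCN probe sets, a fit limited to probe sets above the dim filter, was added only after the adjusted p-values of the unfiltered fit had been seen, and the unfiltered fit was kept as the main one. The test of gene symbol families was also chosen after the data had been seen. All 11 arrays were used.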

Results

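The series followed mRNA levels in IMR32 neuroblastoma cells after transduction with a control virus or a virus carrying a hairpin against MYCN. It comprised 2 arrays without virus, 1 control virus array at each of 24, 48 and 72 hours, and 2 arrays labelled shMYCN at each of these 3 times. Median signals lay between 14.9 and 16.7 on the 11 arrays, and the 3' to 5' ratio of the GAPDH control probe sets lay between 0.97 and 1.07. Replicate arrays correlated at r = 0.987 to 0.995 across genes, which are not independent replicates. The pair labelled shMYCN at 48 hours was the most dissimilar, with a standard deviation of its log2 differences of 0.271, against 0.172 for the pair without virus. On array A of that pair, probe sets for the bacterial poly-A spike RNAs were 2.67-fold above the mean of the 5 untreated and control arrays. Probe sets for the hybridization spikes were 1.22-fold above theirs on it.

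MYCN encodes the transcription factor amplified in these cells and is the target of the hairpin, and its mRNA was examined first as a check of the labels. MYCN had 10 probe sets, of which 4 lay above the dim filter. None of the 10 passed as lower in the arrays labelled shMYCN against the control virus, at any hour or as a mean. The brightest MYCN probe set, at the 99.7 percentile of all signals, measured 5028 ± 651 (SD, n = 2) at 24 hours, 5279 ± 53.4 at 48 hours and 5285 ± 479 at 72 hours in those arrays. The single control virus arrays gave 5332, 5389.7 and 5055 at the same times, and the arrays without virus gave 4774 ± 377 (SD, n = 2). The log2 fold change over the 3 times was -0.020 ± 0.09 (limma adjusted p = 0.924), while under quantile normalization MYCN expression was higher by 0.12 and passed (limma adjusted p = 0.0111). Whether signal still followed RNA amount at this brightness was not tested.

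The second brightest MYCN probe set measured 273 ± 26.9 (SD, n = 2) at 24 hours, 472 ± 216 at 48 hours and 723 ± 102 at 72 hours in the arrays labelled shMYCN. Control virus arrays gave 406, 520.1 and 370.4, and the arrays without virus gave 363 ± 11.3 (SD, n = 2). The log2 fold change of this MYCN probe set against control virus was -0.55 ± 0.31 at 24 hours (limma adjusted p = 0.663), -0.21 ± 0.31 at 48 hours (limma adjusted p = 0.797) and 0.93 ± 0.31 at 72 hours (limma adjusted p = 0.0996), and none of these passed. In a fit limited to probe sets above the dim filter, chosen after these values had been seen, the limma adjusted p at 72 hours was 0.0254. Among alternatives fixed beforehand, the limma adjusted p at 72 hours was 0.0257 with the letters as a block and 0.140 without trend. Leaving out array A or B of 48 hours left the fold of this probe set at 0.93 at 72 hours. The change from 24 to 72 hours stayed at 1.48. Neither array enters these folds, and their p-values fell only through the estimated spread, which no longer held this unlike pair (319.4 and 624.2). For the next MYCN probe set the log2 fold change was -0.52 ± 0.31 at 24 hours (limma adjusted p = 0.676) and 0.68 ± 0.31 at 72 hours (limma adjusted p = 0.214). The fold at 72 hours was again unchanged without array A or B of 48 hours. The last MYCN probe set above the dim filter gave -0.35 ± 0.28 at 24 hours, -0.14 ± 0.28 at 48 hours and 0.17 ± 0.28 at 72 hours, and none of these passed.

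Within the arrays labelled shMYCN, the second MYCN probe set rose between 24 and 72 hours by 1.35 ± 0.25 on the log2 scale (limma adjusted p = 0.0106). The call was lost when any one of the 4 arrays was left out, which left 1 array in a group. The rise itself then lay between 1.21 and 1.49. The next MYCN probe set rose by 1.26 ± 0.25 over the same interval (limma adjusted p = 0.0133), a call lost in the same way, with rises between 1.11 and 1.40. Against no virus, 1 of the 6 MYCN probe sets below the dim filter was lower (log2 -0.34 ± 0.06, limma adjusted p = 0.00893), at a mean signal of 5.25 without virus, and the control virus arrays gave -0.30 ± 0.07 for it, which did not pass (limma adjusted p = 0.720). The position of the probe sets relative to the site of the hairpin was not known here. As no fall of MYCN mRNA passed against the control virus, the arrays are called labelled shMYCN throughout, and directions given for them rest on the label.

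**Figure D1:**
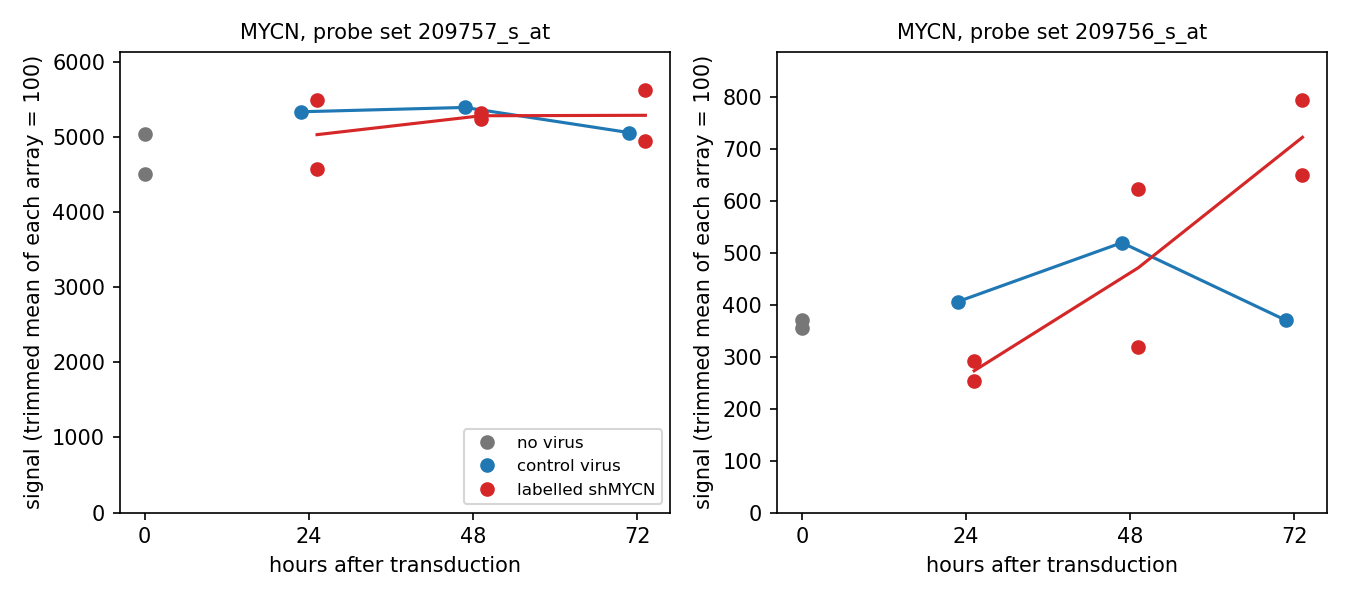
Signal of the brightest (left) and second brightest (right) MYCN probe set (linear, trimmed mean of each array at 100) against hours after transduction. Points are single arrays and lines join group means. In the arrays labelled shMYCN the right panel has means of 273, 472 and 723 at 24, 48 and 72 hours.

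The main comparison asked which genes differed between the arrays labelled shMYCN and the control virus, as a mean over the 3 times. STMN2, a microtubule regulator of growing axons, led the rises at 4.13-fold (log2 2.05 ± 0.08, limma adjusted p = 3.08e-08), and ABAT, which breaks down the transmitter GABA, was 3.11-fold higher. CDKN1C, which encodes the cyclin-dependent kinase inhibitor p57, rose 2.71-fold. The other rises named by the rule were B3GALT2 (log2 1.46), ADGRG1 (1.38), MBD5 (1.38), ENPP2 (1.36), PLEKHA6 (1.30), LINC01828 (1.29), the tubulin-binding TPPP3 (1.28), the microtubule stabilizer MAP6 (1.27) and the RNA-binding protein gene CELF3 (1.27). For PLEKHA6 and TPPP3 the reference signals lay under about 14.8, the mean signal at the dim filter. PLEKHA6 measured 1.5 without virus and 2.2, 10.8 and 2.9 in the control virus arrays. TPPP3 measured 4.05 without virus and 2.2, 2.6 and 9.4 in the control virus arrays. A second probe set of MBD5 did not share the rise, at log2 0.029 ± 0.18 for the mean and -0.10 ± 0.31 at 72 hours.

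REEP3, an endoplasmic reticulum protein gene, fell most, with a log2 fold change of -1.95 ± 0.11 (limma adjusted p = 3.46e-07). The autophagosome protein gene GABARAP followed at -1.94 ± 0.06 and the centromere factor gene OIP5 at -1.86 ± 0.09. The small GTPase gene RAP1A gave -1.82, and the respiratory chain subunit genes NDUFB2 and COX5B gave -1.82 and -1.64. ID3, an inhibitor of basic helix-loop-helix transcription factors, gave -1.69, and MAF1, a repressor of RNA polymerase III, gave -1.63. The remaining named falls were EPDR1 (-1.75), SMCO4 (-1.71), MEX3D (-1.67) and STC1 (-1.62). Among the 24 genes, 13 had other probe sets, 22 in number, of which 21 had the sign of the representative and 18 of these were also called. The exception was a probe set of NDUFB2, at 0.065 ± 0.11, while another NDUFB2 probe set gave -2.01 ± 0.07.

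In total, 4500 of 11865 genes passed limma's test, 2629 higher and 1871 lower, and 146 of them changed at least 2-fold (45 higher, 101 lower). Median scaling turned the split to 2129 higher and 2235 lower, so no excess of either direction is claimed. Without the control virus array of 72 hours the mean of the other hours called 1938 genes. All 6 arrays labelled shMYCN lay on one side of the control of their hour for 3372 of the 4500, or 74.9 percent, which describes these genes and is no test, since they were selected on the same arrays. Each hour had a single control array, so the spread between control cultures is not in these p-values.

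**Figure D2:**
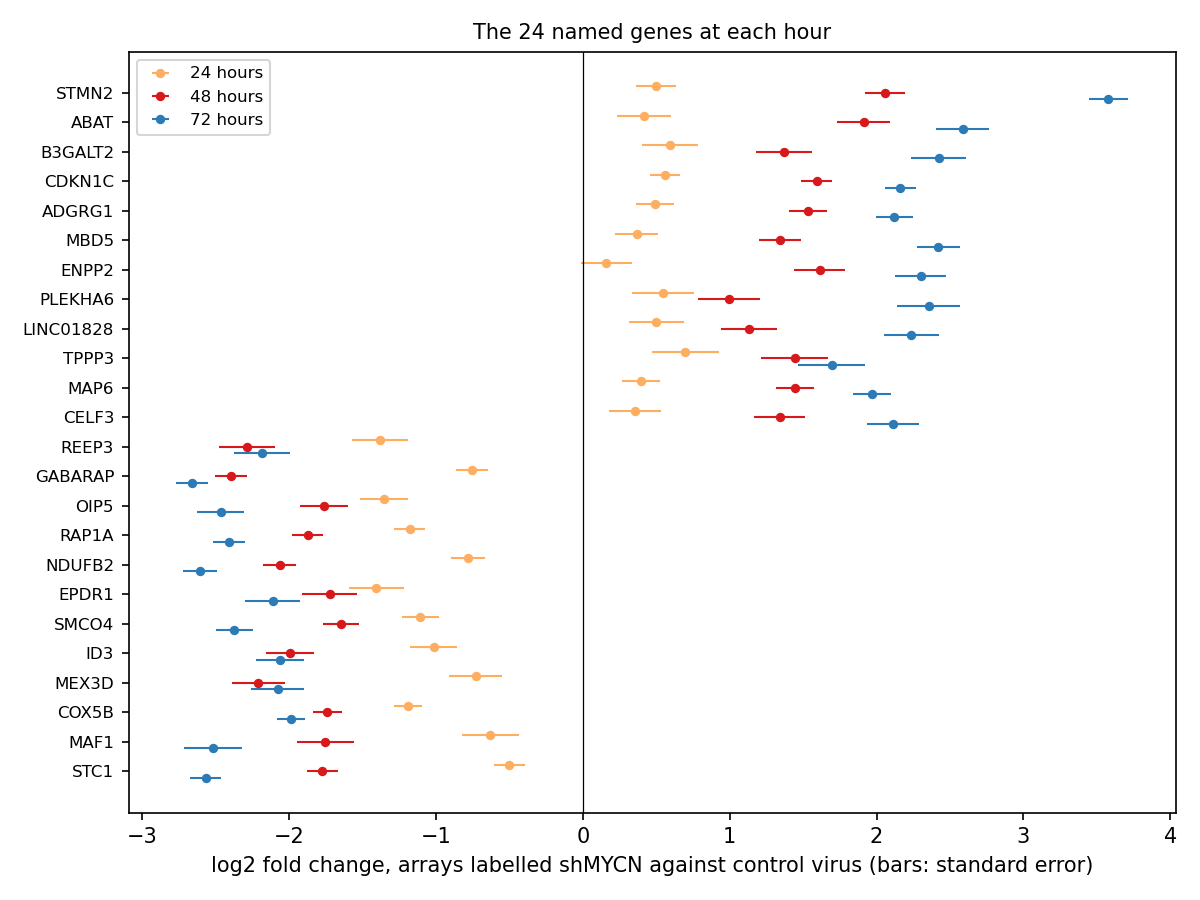
Log2 fold change (x axis) of the 24 named genes at 24, 48 and 72 hours in the arrays labelled shMYCN against the control virus array of the same hour. Points are fitted values and bars are standard errors, and STMN2 went from 0.50 at 24 hours to 3.58 at 72 hours.

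DNA replication and G1/S genes, which license origins and copy the genome, fell most clearly among the lists fixed before the data were examined. The replicative helicase genes MCM3 (log2 -1.14) and MCM5 (-0.95), the cyclin gene CCNE2 (-1.18) and the origin recognition gene ORC1 (-0.86) had the smallest p. Of 46 measured DNA replication members, 33 were lower, 1 was higher and 12 did not pass, with 36 lower and 1 higher when adjusted over the list alone (median log2 -0.30, camera adjusted p = 4.15e-12, and 0.0205 with an estimated correlation). This was the one list of 23 whose shift in the main comparison passed with an estimated correlation.

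Nucleotide and polyamine synthesis, ribosome biogenesis and mitosis serve growth and division. The ribonucleotide reductase gene RRM2 fell (log2 -1.07), as did the purine synthesis genes ADSL (-0.77), IMPDH2 (-0.73) and GMPS (-0.56). Of the nucleotide and polyamine list, 20 of 31 members were lower and none higher, with 21 lower and 1 higher adjusted over the list alone (median -0.30, camera adjusted p = 1.94e-07, adjusted p = 0.0796 with an estimated correlation). Ribosome biogenesis genes fell with LYAR (-1.25), GAR1 (-0.89), PNO1 (-0.49) and NOC4L (-0.64) in front, and 24 of 48 were lower and none higher, also adjusted over the list alone (median -0.21, camera adjusted p = 5.36e-07, adjusted p = 0.0585 with an estimated correlation). G2/M and mitosis genes such as KIF23 (-0.96), ANLN (-0.81), FOXM1 (-0.53) and KIF4A (-0.55) fell, with 19 of 46 lower and 2 higher, and 23 and 3 adjusted over the list alone (median -0.15, camera adjusted p = 6.95e-06, adjusted p = 0.0585 with an estimated correlation).

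Canonical MYC-activated genes are textbook targets of MYC proteins, and mesenchymal markers mark the less neuronal state of neuroblastoma cells. TFB2M (log2 -0.97), PRDX3 (-0.63), ENO1 (-0.56) and CDC25A (-0.68) fell among the canonical MYC-activated genes, of which 12 of 28 were lower and none higher, with 13 lower adjusted over the list alone (median -0.20, camera adjusted p = 4.35e-05, adjusted p = 0.312 with an estimated correlation). SNAI2 (-1.18), COL4A1 (-0.76), YAP1 (-0.89) and COL5A1 (-0.62) fell among the mesenchymal markers, of which 11 of 20 were lower and 2 higher, with 12 and 2 adjusted over the list alone (median -0.29, camera adjusted p = 7.20e-05, adjusted p = 0.0585 with an estimated correlation).

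Neuronal differentiation was the one list shifted upward. After STMN2, its members with the smallest p were the neuronal migration gene DCX (log2 1.26), the cell adhesion gene CNTN1 (1.06) and the dendritic microtubule gene MAP2 (0.81). Of 41 measured neuronal genes, 21 were higher and 3 lower, with 21 and 4 adjusted over the list alone (median 0.25, camera adjusted p = 1.90e-04, adjusted p = 0.173 with an estimated correlation).

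Another 6 lists of protein synthesis, RNA processing and metabolism were shifted downward. EIF2S2 (log2 -1.25), IARS1 (-0.80), EIF6 (-0.61) and YARS1 (-0.68) fell among translation factors and tRNA synthetases (14 of 30 lower, 1 higher, with 15 and 1 adjusted over the list alone, camera adjusted p = 4.35e-05). SF3A3 (-0.71), WDR77 (-0.77), SRSF3 (-0.42) and U2AF1 (-0.37) fell among splicing factors (10 of 28 lower, also over the list alone, camera adjusted p = 2.49e-05). CCT7 (-0.63), DNAJA1 (-0.45), HSPH1 (-0.37) and CCT2 (-0.37) fell among heat shock proteins and chaperonin (6 of 19 lower, 5 over the list alone, camera adjusted p = 3.66e-04). In glycolysis PFKM (-1.35), ENO1 (-0.56) and ALDOA (-0.47) fell while the neuronal enolase gene ENO2 rose (0.79), with 10 of 20 lower and 2 higher, and 11 and 2 over the list alone (camera adjusted p = 5.35e-04). In the mitochondrial respiratory chain COX5B (-1.64), NDUFS1 (-0.59) and NDUFA8 (-0.32) fell and COX7C rose (0.58), with 7 of 38 lower and 1 higher, and 5 and 1 over the list alone (camera adjusted p = 0.0142). No ribosomal protein gene of 44 passed, alone or over all genes, and the smallest p were those of RPS28 (-0.19), RPL36 (0.16), RPS18 (-0.18) and RPS14 (-0.20), although the list was shifted (median -0.10, camera adjusted p = 0.00883). With an estimated correlation the adjusted p-values of these 6 lists, in the order given, were 0.216, 0.312, 0.399, 0.251, 0.511 and 0.779, and the ribosomal protein shift changed sign under quantile normalization.

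MYC network members, which comprise the partners and antagonists of MYC proteins, the related MLX branch and the MYCN antisense transcript MYCNOS, passed in 2 of 10 cases (camera adjusted p = 0.832, the same 2 adjusted over the list alone). MXI1, a MAX-binding antagonist of MYC, rose (log2 0.40 ± 0.06) and MLX fell (-0.21 ± 0.06). The other values were 0.22 for MXD1, 0.22 for MYCNOS, 0.14 for MAX, -0.13 for MLXIP, 0.056 for MXD3, 0.021 for MYCL, -0.015 for MNT and -0.020 for MYCN. Genes described as repressed by MYC or MYCN were not shifted (7 of 20 higher and 5 lower, 8 and 5 over the list alone, camera adjusted p = 0.547): CCNG2 (0.69), GADD45A (0.56) and DKK3 (0.71) rose and CD9 fell (-0.83). Among CDK inhibitors and pocket proteins CDKN1C, CCNG2 and RBL2 (0.60) rose and CDKN1A fell (-0.39), with 5 of 9 not passing (camera adjusted p = 0.622, the same over the list alone). Among p53 targets GADD45A, TP53INP1 (0.65) and ZMAT3 (0.41) rose and SESN2 fell (-0.57), with 4 of 23 higher and 2 lower, also over the list alone (camera adjusted p = 0.919).

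Noradrenergic identity genes, which mark the sympathetic origin of neuroblastoma, went both ways: LMO3 (log2 0.98), DDC (0.70) and LIN28B (0.62) rose and the noradrenaline transporter gene SLC6A2 fell (-0.92). Of 23, 6 were higher and 6 lower, also over the list alone (camera adjusted p = 0.919). Interferon and virus response genes had IFIT5 (-1.27) and USP18 (-0.62) lower and IFI44 (0.33) and RIGI (0.41) higher, with 11 of 15 not passing, the same over the list alone (camera adjusted p = 0.919). In the integrated stress and unfolded protein response MANF (-0.56) and CEBPB (-0.60) fell and TRIB3 (0.60) and DDIT4 (0.53) rose, with 3 of 28 higher and 5 lower, also over the list alone (camera adjusted p = 0.173). In cholesterol synthesis HMGCS1 (-1.02) and DHCR7 (-0.71) fell and INSIG1 (0.40) and MSMO1 (0.34) rose, with 14 of 18 not passing, the same over the list alone (camera adjusted p = 0.591).

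In lysosome and autophagy LAMP2 fell (log2 -0.84) and ATP6V1H (0.35), MAP1LC3B (0.41) and WIPI1 (0.65) rose, with 7 of 24 higher and 2 lower, and 8 and 2 over the list alone (camera adjusted p = 0.257). In the BCL2 family, which controls cell death, MCL1 (-0.70) and BID (-0.35) fell and BCL2L11 (0.66) and BCL2 (0.41) rose, with 2 of 13 higher and 3 lower, also over the list alone (camera adjusted p = 0.570). Schwann and glial markers had 1 measured gene, GAS7 (0.14), and leukocyte markers had 2, CD79A (0.057) and FCER1G (0.030). None of these passed, and the lists were too short to test.

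**Figure D3:**
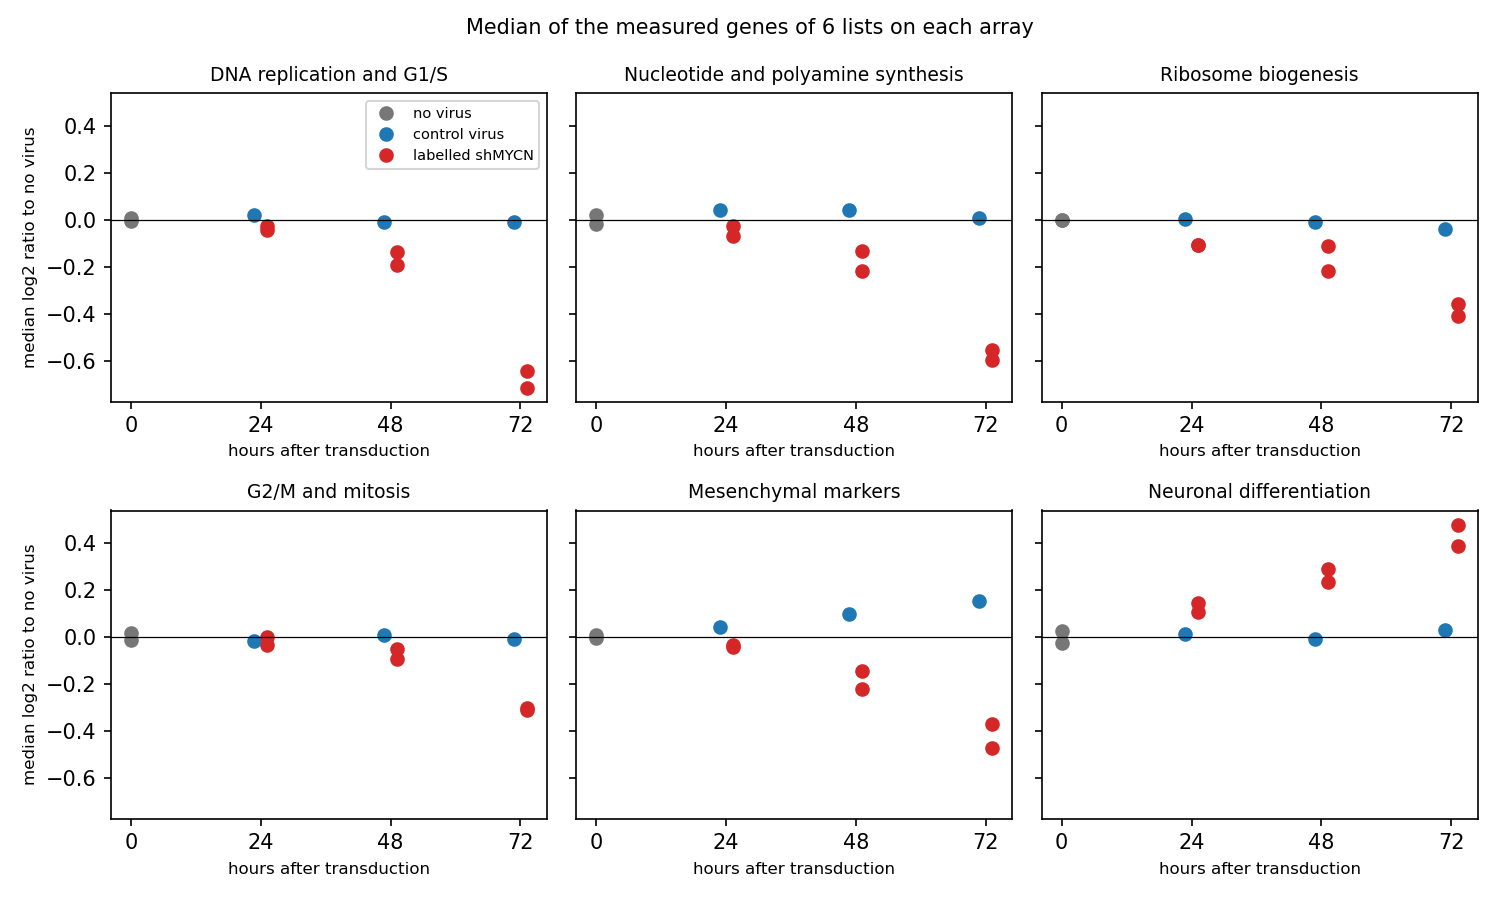
Median log2 ratio to the mean of the arrays without virus (y axis) of the measured genes of 6 lists on each array, against hours after transduction. Points are single arrays. The DNA replication median of the arrays labelled shMYCN lies lowest and the neuronal median highest at 72 hours.

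At 24 hours the earliest differences were found, led by a fall of E2F5, a cell cycle transcription factor gene. E2F5 (log2 -1.46 ± 0.13, limma adjusted p = 7.74e-04), EPDR1 (-1.41), REEP3 (-1.38), OIP5 (-1.35) and MTLN (-1.22) fell most. The axon guidance gene SEMA5B (1.31 ± 0.19, limma adjusted p = 0.00951), LOC105274304, PLPP7 (1.11), FTX (1.02) and GPR155 (0.92) had the largest upward differences. Much of these 5 came from a low control array: against no virus the control virus array of 24 hours lay at -0.78 for SEMA5B, -0.89 for LOC105274304, -0.79 for PLPP7, -0.50 for FTX and -0.79 for GPR155, and the arrays labelled shMYCN at 0.53, 0.30, 0.32, 0.52 and 0.13. In shMYCN against control virus at 24 hours, 84 genes passed, 14 higher and 70 lower. All 70 lower genes were also called lower at 72 hours and 12 of the 14 higher genes higher, in a comparison that shares no array but shares the fitted spread, while GPR155 was called in opposite directions, with a signal of 44.4 on the control array of 24 hours against 88.2 without virus and 98.2 in the arrays labelled shMYCN. The 4 other probe sets of FTX, GPR155 and REEP3 had the same sign, and none passed at 24 hours. Canonical MYC-activated genes, ribosome biogenesis, ribosomal proteins, translation factors, nucleotide synthesis, heat shock proteins, the respiratory chain and splicing factors were shifted downward at a preset correlation, and none of these 8 lists passed with an estimated one. Against no virus, array A lay near the control array for ribosomal proteins (0.14 and 0.16), canonical MYC-activated genes (0.074 and 0.10) and splicing factors (0.080 and 0.079). Array B lay at -0.090, -0.10 and -0.068 for them. For ribosome biogenesis arrays A and B both lay at -0.11 and the control array at 0.0032. The count was 3 without array A of 24 hours, 14 without array B, and 401 without array A of 48 hours, which changes the estimated spread.

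At 48 hours the neuronal gene STMN2 (log2 2.06 ± 0.13, limma adjusted p = 9.55e-06), ABAT (1.91), ENPP2 (1.61), CDKN1C (1.59) and TMEM150C (1.54) rose most. GABARAP (-2.40 ± 0.11), REEP3 (-2.29), MEX3D (-2.21), NDUFB2 (-2.06) and ID3 (-2.00) fell most. All 11 other probe sets of these genes had the same sign and 8 were called, while a second TMEM150C probe set gave 0.47 ± 0.23 and did not pass, and the control array measured 22.5 for TMEM150C against 45.9 without virus. In shMYCN against control virus at 48 hours, 2015 genes passed, 1196 higher and 819 lower, and median scaling turned this split to 962 higher and 1032 lower. DNA replication genes had 9 of 46 lower and 1 higher (adjusted p = 0.107 with an estimated correlation), and none of the 12 lists shifted at a preset correlation, 11 lower and neuronal differentiation higher, passed with an estimated one. Array A of 48 hours, with its raised poly-A spikes, took part in these values, and without it 2302 genes passed.

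At 72 hours the neuronal gene STMN2 was highest again (log2 3.58 ± 0.13, limma adjusted p = 1.45e-07), followed by ABAT (2.59), B3GALT2 (2.42), MBD5 (2.42) and CT75 (2.40). GABARAP was lowest (-2.66 ± 0.11), followed by NDUFB2 (-2.61), STC1 (-2.57), MAF1 (-2.52) and OIP5 (-2.47). Of 10 other probe sets of these genes 8 had the same sign and 6 were called, and those of CT75 (0.51 ± 0.19) and one of ABAT (0.57 ± 0.24) did not pass. The control array of 72 hours lay below no virus for CT75 (108.7 against 215.7) and above it for STC1 (901.5 against 376.5). At this time 4034 genes passed, 2166 higher and 1868 lower (1969 and 1981 under median scaling), and 711 changed at least 2-fold. DNA replication and G1/S genes had 39 of 46 members lower and none higher (median log2 -0.61, adjusted p = 0.00937 with an estimated correlation), and G2/M and mitosis genes had 22 of 46 lower and 1 higher (median -0.32, adjusted p = 0.0452 with an estimated correlation). These were 2 of the 12 lists shifted at a preset correlation, 11 of them lower. Without array A of 72 hours 2896 genes passed.

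**Figure D4:**
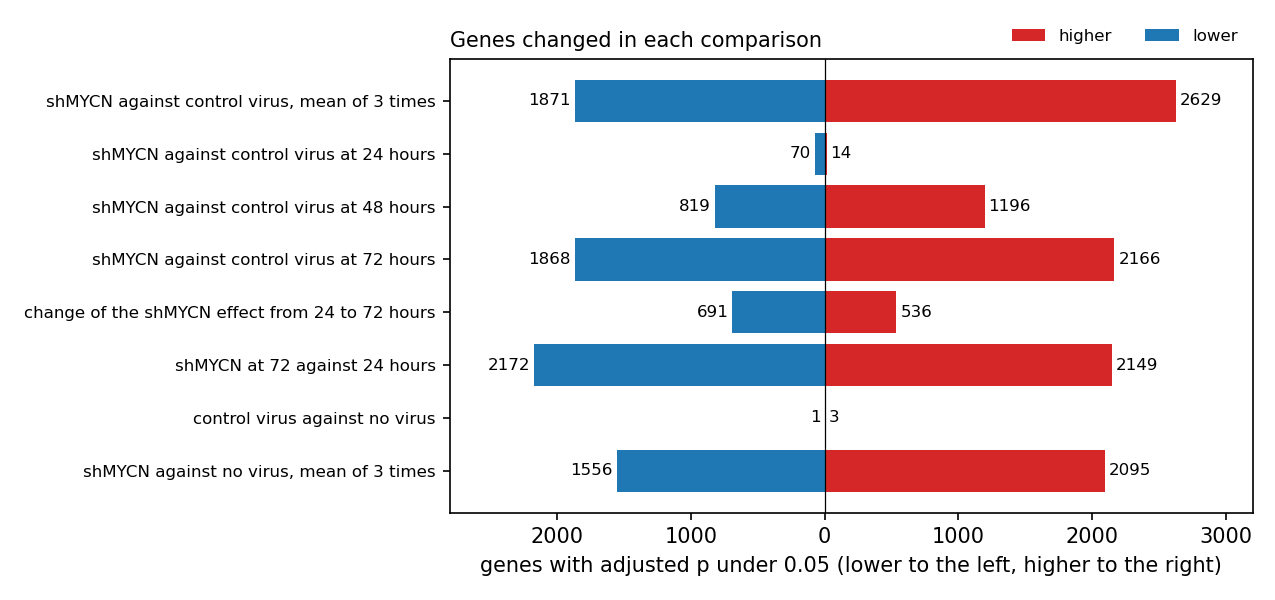
Number of genes (x axis) past an adjusted p of 0.05 in each of the 8 comparisons, with lower genes drawn to the left and higher genes to the right of 0. Control virus against no virus has 4 genes and the mean over 3 times has 4500.

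STMN2 also led the change of the shMYCN effect from 24 to 72 hours (3.08 ± 0.19, limma adjusted p = 4.02e-05), followed by CHODL (2.59), CT75 (2.48), DEPP1 (2.19) and the neuropeptide receptor gene MCHR1 (2.19). SUSD2 (-2.37 ± 0.20), NT5DC2 (-2.26), STC1 (-2.07), AK4 (-1.91) and GABARAP (-1.91) changed most downward. For SUSD2 and STC1 most of this was a rise in the control virus arrays (SUSD2 from 110.0 to 362.4, STC1 from 385.1 to 901.5), and the arrays labelled shMYCN moved by -0.79 and -0.87. A second CT75 probe set gave 0.44 ± 0.27 and did not pass, and of 8 other probe sets of the named genes 8 had the same sign and 5 were called. The change passed for 1227 genes, 536 upward and 691 downward. DNA replication genes had 24 of 46 members with a downward change and none upward (adjusted p = 0.00701 with an estimated correlation), and G2/M genes 12 of 46 (adjusted p = 0.0405), 2 of 10 lists shifted at a preset correlation. Without any one array labelled shMYCN at 24 or 72 hours the count lay between 557 and 626.

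Within the arrays labelled shMYCN, STMN2 (log2 2.91 ± 0.11, limma adjusted p = 1.71e-07), CHODL (2.67), PMEL (2.36), ADGRG1 (2.18) and SPOCK1 (2.18) rose most from 24 to 72 hours. NT5DC2 (-2.27 ± 0.14), ID1 (-2.19), which like ID3 inhibits basic helix-loop-helix factors, GABARAP (-2.13), NDUFB2 (-2.01) and ID3 (-1.99) fell most. In all 4321 genes passed, 2149 higher and 2172 lower. DNA replication genes had 42 of 46 lower and none higher (adjusted p = 0.00762 with an estimated correlation) and G2/M genes 28 lower and 1 higher (adjusted p = 0.0362), 2 of 13 lists shifted at a preset correlation. This comparison has no control at each hour and includes time in culture. Without array A of 24 hours 2648 genes passed.

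Control virus against no virus measured the virus together with time in culture. SUSD2 (log2 0.91 ± 0.11), the nicotinic receptor gene CHRNA1 (0.84 ± 0.10) and STC1 (0.66 ± 0.08) rose and MARCHF11, a ubiquitin ligase gene, fell (-0.58 ± 0.08). These were the 4 genes that passed, with limma adjusted p-values of 0.0166 for each rise and 0.0412 for the fall, and quantile normalization gave 3 higher and 4 lower. The 4 other probe sets of SUSD2, CHRNA1 and STC1 had the same sign, and none passed. Cholesterol synthesis genes were shifted upward as a list (18 measured, median log2 0.19, camera adjusted p = 1.07e-11, adjusted p = 0.0439 with an estimated correlation), although no member passed over all genes and 3 passed over the list alone. Ribosomal proteins, glycolysis, canonical MYC-activated genes, mesenchymal markers and the integrated stress response were shifted upward at a preset correlation alone, with no member past the threshold, and quantile normalization turned the direction of the ribosomal protein and canonical MYC-activated lists. No gene passed when either array without virus was left out.

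In shMYCN against no virus, mean of 3 times, STMN2 (log2 1.85 ± 0.09, limma adjusted p = 3.13e-07), ADGRG1 (1.72), ABAT (1.66), the neuronal migration gene DCX (1.58) and PLEKHA6 (1.56) rose most. ID3 (-2.09 ± 0.11), EPDR1 (-1.91), GABARAP (-1.91), RAP1A (-1.87) and OIP5 (-1.86) fell most. In all 3651 genes passed, 2095 higher and 1556 lower, a split that median scaling turned to 1730 higher and 1833 lower. DNA replication and G1/S had 25 of 46 members lower and 1 higher, with 31 and 1 over the list alone (adjusted p = 0.0201 with an estimated correlation), the one list to pass so of 12 shifted at a preset correlation. This comparison shares its arrays labelled shMYCN with the main one and is not independent of it. Without array 1 or array 2 of the cells without virus the counts were 1769 and 1752.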

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

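The tests of swapped arrays, scaling at 72 hours and a deviating control culture were chosen after the results they bear on were seen. The reading of the test of the neighbours of MYCN was set after its value was seen. That test and the other tests here were chosen before their own values were seen. The test of the neighbours and those of the excess of lower genes at the earliest hour bear on patterns read from these data.

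The second brightest MYCN probe set was higher at 72 than at 24 hours in arrays labelled shMYCN, a call lost without any single array of those hours. In those fits, with 1 array left in a group, its log2 rise lay between 1.21 and 1.49. Its signal lay below control virus at 24 hours (273 against 406) and above it at 72 hours (723 against 370.4). Neither difference passed (limma adjusted p = 0.663 and 0.0996). The brightest MYCN probe set did not rise between 24 and 72 hours (log2 0.075 ± 0.12, limma adjusted p = 0.789). On both arrays labelled shMYCN at 72 hours the DNA replication list had a median of -0.62 log2 or lower against the control array. That fall was already known, and reading it against a swap assumes that the hairpin lowers these genes, so it cannot decide. The fold at 72 hours depended little on scaling, with a smallest log2 fold over 3 scalings of 0.90 ± 0.30. These scalings moved the median of all genes only between 0.036, 0.023 and 0.010, so a large change was not possible. Whether the whole amplified region rose cannot be told apart: the neighbours DDX1, NBAS and CYRIA had log2 folds of -0.25, -0.10 and 1.23, a median of -0.10 with a spread of 1.48, and members that go both ways decide nothing. The position of the probe sets relative to the hairpin site, and an effect on protein rather than mRNA, were not tested.

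Of the genes called at 24 hours, 70 of 84 were lower. In the arrays labelled shMYCN these lower genes had a median log2 fold of -0.76 against no virus, and 70 of 70 lay below 0. The genes were selected on these same arrays, so this is partly built in. The control array lay at a median of 0.022 against no virus for them, with 40 of 70 above 0. For these lower genes that argues against a deviating control array. For the 14 higher genes the part of the control array stays open, since it lay at a median of -0.49 against no virus and the arrays labelled shMYCN at 0.41. The medians of the control array were computed after the calls were seen. Over quantile and median scaling 89.2 percent were lower at the least. These scalings moved the median of all genes at 24 hours only from 0.027 to 0.015 and -0.025. A large change was thus not possible, and the test cannot decide on scaling. Only 2 of the 70, MCM3 and TFB2M, were members of the 4 MYC-related lists, where 0.861 was expected (one-sided Fisher exact p = 0.213), so their part in the pattern cannot be told apart from chance with so few. Direct targeting of these transcripts by the hairpin may contribute and was not tested, since no sequences were used here.

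The main comparison called 4500 genes, and 1938 without the control virus array of 72 hours. Of 27 choices of 1 array per hour as the control, only the real 1 gave as many. The highest other gave 2889, a choice that kept the real controls of 48 and 72 hours. In the additive model of virus and hour, only the real 1 of 81 splits of the 9 transduced arrays gave as many as 3001. The highest other gave 1160, and 3 of 84 splits could not be fitted. Both tests exchange single arrays, so neither can exclude chance differences between cultures. A control culture that deviates as a whole is argued against by 3651 genes for shMYCN against no virus beside 4 for control virus against no virus. That the hairpin acts through targets other than MYCN stays open, as the design has 1 hairpin.

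The effect of the label differed between 24 and 72 hours, by the test of the change itself, for 1227 genes. Among lists, median changes were -0.60 for DNA replication and G1/S, -0.54 for mesenchymal markers, -0.48 for nucleotide and polyamine synthesis, -0.34 for glycolysis, -0.29 for G2/M and mitosis, -0.25 for ribosome biogenesis, -0.22 for translation factors, -0.22 for cholesterol synthesis, -0.18 for splicing factors and 0.33 for neuronal differentiation. With an estimated correlation the changes of DNA replication (adjusted p = 0.00701) and G2/M (adjusted p = 0.0405) passed. Upward changes in log2 were 3.08 for STMN2, 2.59 for CHODL, 2.48 for CT75, 2.19 for DEPP1, 2.19 for MCHR1, 2.17 for ABAT, 2.14 for ENPP2, 2.05 for MBD5, 1.83 for B3GALT2, 1.81 for PLEKHA6, 1.76 for CELF3, 1.74 for LINC01828, 1.63 for ADGRG1, 1.60 for CDKN1C and 1.57 for MAP6. Downward changes were -2.37 for SUSD2, -2.26 for NT5DC2, -2.07 for STC1, -1.91 for AK4, -1.91 for GABARAP, -1.89 for MAF1, -1.83 for NDUFB2, -1.35 for MEX3D, -1.27 for SMCO4, -1.23 for RAP1A, -1.11 for OIP5, -1.04 for ID3 and -0.80 for COX5B. For SUSD2 and STC1 most of the change came from a rise in the control virus arrays.

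The poly-A spike probe sets, outside the gene tests, lay above the highest untreated or control array on 4 arrays labelled shMYCN: 2.67-fold on A at 48 hours, 1.40-fold on A at 72 hours, 1.15-fold on A at 24 hours and 1.10-fold on B at 72 hours, relative to the mean of the 5 untreated and control arrays. On the same arrays, in that order, the hybridization spike probe sets lay at 1.22-fold, 0.99-fold, 1.12-fold and 1.00-fold of their own mean on those 5 arrays.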

How the results depend on the processing

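The fit of MYCN probe sets above the dim filter was chosen after the data were seen, and the other alternatives were chosen before. It took the second MYCN probe set past the threshold at 72 hours (adjusted p = 0.0254) and for the change from 24 to 72 hours (adjusted p = 0.0418), and the cause was not tested. With the letters as a replicate block its adjusted p at 72 hours was 0.0257, and it was 0.140 without trend. Over all tested genes A minus B correlated between hours at -0.051, 0.038 and 0.10, which cannot show whether the letters pair cultures. For the second MYCN probe set array B lay above array A at each hour (292.3 against 254.2, 624.2 against 319.4 and 795.6 against 650.7).

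Apart from leave-outs, of the results for named genes 2083 kept direction and side of the threshold, 119 lost the call, 11 gained it and 7 changed direction. Of the list results 637 kept both, 86 lost the call and 9 changed direction. Of the counts of genes or lists 81 stayed within 1.5 times, 24 were lower and 5 higher. The direction of a list is that of its test and can differ from the sign of its median. The 7 gene results and 9 list results that changed direction had not passed, except ribosomal proteins in both comparisons and canonical MYC-activated genes against no virus.

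Quantile normalization gave 7 genes for control virus against no virus. It gave MYCN expression of 0.12 (adjusted p = 0.0111), past the threshold upward, and MYCL, shMYCN against control virus, mean of 3 times, of -0.022. List medians relative to all genes became 0.0044 for list Ribosomal proteins, shMYCN against control virus, mean of 3 times, -0.0061 for list Noradrenergic identity, shMYCN against control virus, mean of 3 times, 0.0059 for list Canonical MYC-activated genes, control virus against no virus, and -0.019 for list Ribosomal proteins, control virus against no virus. Median scaling gave -0.019 for MYCL and -0.010 for FCER1G, shMYCN against control virus, mean of 3 times. The cause was not tested.

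With no filter on dim genes the counts were 35 for shMYCN against control virus at 24 hours, 651 for the change of the shMYCN effect from 24 to 72 hours and 0 for control virus against no virus, with more genes to adjust for. List p53 target genes, shMYCN against control virus, mean of 3 times, lay at -0.0092 with no filter, 0.070 with 60 percent left out and -0.013 with the mean of probe sets. List Noradrenergic identity, shMYCN against control virus, mean of 3 times, lay at 0.016 with no filter and 0.050 with the mean of probe sets. That mean also gave -0.046 for MAX, shMYCN against control virus, mean of 3 times, 0.19 for RPS28, shMYCN against control virus, mean of 3 times (adjusted p = 0.0205), -0.13 for CD79A, shMYCN against control virus, mean of 3 times, and counts of 48 at 24 hours and 2 for control virus against no virus. The cause was not tested.

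Counting every probe set on its own gave 7430 for shMYCN against control virus, mean of 3 times, 6404 for shMYCN against control virus at 72 hours, 6989 for shMYCN at 72 against 24 hours and 5755 for shMYCN against no virus, mean of 3 times, as probe sets rather than genes. A variance model without trend gave 35 for shMYCN against control virus at 24 hours and 0 for control virus against no virus, and the cause was not tested.

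By construction, stricter thresholds left fewer genes. An adjusted p under 0.01 and a fold of at least 2 left 2846 and 146 for shMYCN against control virus, mean of 3 times, 25 and 20 for shMYCN against control virus at 24 hours, 847 and 198 for shMYCN against control virus at 48 hours, 2441 and 711 for shMYCN against control virus at 72 hours, 370 and 406 for the change of the shMYCN effect from 24 to 72 hours, 2658 and 390 for shMYCN at 72 against 24 hours, 0 and 0 for control virus against no virus, and 2144 and 167 for shMYCN against no virus, mean of 3 times. An estimated correlation left 1 of the 13 gene list shifts.

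Where a leave-out left 1 array in a group, that array was assumed to vary like the others, and without letter A or B 1 residual degree of freedom was left. The lowest and highest counts were 1938 (without control virus at 72 hours) and 5684 (without letter B) for the mean of 3 times, 3 and 595 at 24 hours, 1556 and 4291 at 48 hours, 2896 and 5183 at 72 hours, 557 and 2597 for the change, 2648 and 5489 for shMYCN at 72 against 24 hours, 0 and 157 for control virus against no virus, and 1752 and 5150 for shMYCN against no virus. List shifts numbered 11 to 13.

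Over leave-outs, values in shMYCN against control virus, mean of 3 times, that changed direction ranged from -0.19 to 0.22 for MXD3, -0.099 to 0.14 for MYCL, -0.070 to 0.041 for MNT, -0.0013 to 0.29 for RPL36, -0.011 to 0.13 for CD79A, -0.029 to 0.073 for FCER1G and -0.091 to 0.052 for MYCN expression. Among lists they ranged from -0.037 to 0.090 for MYC network, -0.063 to -0.019 for p53 target genes and -0.16 to 0.028 for cholesterol synthesis. The cause was not tested.

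Dim signals limit what can be seen: 7910 of 19775 genes lay below the filter and were not tested in the main setting.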

Other observations

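The test of gene symbol families was chosen after other results had been seen and before its own. Outside the fixed lists, genes of intraflagellar transport, which carry cargo along cilia, were higher in the arrays labelled shMYCN: 12 of 17 measured IFT genes rose and none fell (median log2 0.39), with IFT20, IFT22 and IFT27 at the smallest p. Semaphorins, which guide axons, had 9 of 14 members higher and none lower (median log2 0.34), with SEMA4C and SEMA5B at the smallest p.

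These were the 2 symbol stems of 130 that passed camera after the 601 tested genes of the fixed lists were left out (adjusted p = 0.00388 for IFT and 0.0498 for SEMA). Neither passed with an estimated correlation (adjusted p = 0.900 for both), so a shared shift of these families remains a hypothesis.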
